A study of Mus musculus with 8 samples.

How the data were processed

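Microglia were isolated, per the labels' protocols, from perfused brains that were homogenised mechanically in the cold, passed over a strainer and freed of myelin on Percoll. Cells with high CD11b and intermediate CD45 were sorted, and RNA of integrity number 8 or higher was used. Each sample gave 5.775 ng of RNA for amplification with the NuGEN WT-Ovation Pico system, converted to sense cDNA and labelled with biotin for Affymetrix gene arrays that measure whole transcripts. Amplification from so little RNA can add noise and favour some transcripts over others.

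The deposited values are log2 expression values per probe set and array, made with RMA per the submitters' processing notes; the RMA software, its version and the chip library are not given in the sources used here. The log2 base was inferred from the range of the values, 2.04 to 13.99, and not stated. RMA subtracts background, equalises the distributions of the arrays and summarises probes, so a shift shared by all genes cannot be seen, and changes of dim genes are understated. The table held 28874 probe sets for 8 arrays with no missing value, and 0 columns were left unmatched to a sample. By the platform annotation, 21789 probe sets had 1 gene symbol, 1621 had several and 5464 had none; no gene was named from the latter kinds. Symbols were checked by gene number against a RefSeq table of the GRCm38.p6 assembly, which was used for names, gene lengths and gene order only; 21698 probe sets matched and 0 symbols changed. A gene with more than 1 probe set (999 genes) was represented by the one with the highest mean, which left 19938 genes. Among the called genes with more probe sets, Hk1, Tmem167 and Trio had another probe set past an unadjusted p of 0.05 in the opposite direction.

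Samples were grouped by the genotype in the labels, 4 MFP2 knockout and 4 control. The comparison was knockout minus control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test, no covariate, no filter on dim genes), with Benjamini-Hochberg adjustment over all 19938 genes and a threshold of 0.05 on the adjusted p. Standard errors of changes are those of the limma fit, and means are given ± SD. A gene is called higher or lower, or is said to have risen or fallen, when it passed that threshold. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 34 lists; none of the 19 calls held with an estimated correlation, and fry called 12 lists. The lists, the main tests, most alternatives and the rule for naming genes were fixed before the data were examined; the tests and alternatives chosen later are named as such. Of 823 list entries 739 were measured; the others are not analysed here. Lists overlap, so their results are not independent.

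Genes were named by this rule: Hsd17b4; the 10 highest and 10 lowest log2 changes among called genes whose groups did not overlap, leaving out predicted genes, clones, small RNAs, receptor segments and pseudogenes; for each list up to 4 called members by adjusted p, or up to 6 for homeostatic, neurodegeneration-associated, pro-inflammatory and cell cycle genes, or 2 with the lowest p where none passed; 6 identity genes; and the sex-check genes. A few others are named in the text because a list's count was low or because they stood out after their values were seen (S100a8, S100a9, Lyve1, Ms4a7, Colec12, Xbp1, Hsp90b1, Ndufa2 and Csf1r as neighbours of Hsd17b4, and members of gene families).

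The alternatives were a filter on dim genes, quantile normalization, centring of each array, cyclic loess, the mean of a gene's probe sets, all probe sets, an intensity trend with a robust prior, array weights, the replicate number as a block, each array left out in turn, at least 1.5-fold change, an adjusted p under 0.01, a plain two-sample test, other list tests, and 50 or 200 genes on each side of Hsd17b4. The exclusion of control 3 and knockout 2, and of control 1 with them, was added after the data were seen, as were the estimated correlation with arrays left out and, for the genes near Hsd17b4, every alternative other than the 50 or 200 genes. The method was tested on simulated data with the spread of these 19938 genes: for MFP2 knockout against control, of 50 genes changed by each size, 52.0% were recovered at a log2 change of 0.5, 98.0% at 1, 98.0% at 2 and 100% at 3, with 8 false calls among 202. The 41 oxidative phosphorylation genes were shifted as well, by 0.5, and 20 of them are among these calls. Noise was drawn independently for each gene, and far fewer genes were changed than the 1905 called here. These shares therefore do not measure recovery in the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.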

Results

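Gene expression was measured in microglia, the resident macrophages of the brain, sorted from the whole brains of Swiss Webster mice lacking multifunctional protein-2 (MFP2) and of control mice at 17 weeks of age. MFP2, encoded by Hsd17b4, is an enzyme of peroxisomal beta-oxidation, the pathway that shortens very long-chain and branched-chain fatty acids. Cells with high CD11b and intermediate CD45 were taken by flow cytometry, and 1 microarray was made per sample, 4 from knockout and 4 from control animals, all labelled female. Each array gave log2 expression values for 28874 probe sets, from which 19938 genes with a name of their own were tested. The median log2 value of an array lay between 6.03 and 6.15, and the precision of every comparison is limited by the 4 arrays per group. The labels number the replicates without stating that each came from a separate animal, so p-values measure the spread between these samples. The comparison addresses how the microglial transcriptome differs when MFP2 is missing.

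Hsd17b4 was lower in every knockout array than in every control array. Its log2 values were 8.83, 9.09, 8.15 and 7.82 in control 1 to control 4 and 4.76, 7.20, 5.21 and 5.20 in knockout 1 to knockout 4, a difference of -2.88 ± 0.44 (SE) on the log2 scale, or 7.35-fold (limma adjusted p = 0.00158, n = 4 and 4). Knockout 2 was 1.99 above the highest of the other knockout arrays. It is represented by 1 probe set (10455656), whose position relative to the deleted part of the gene is not given in the sources used here, so the residual signal does not measure intact transcript. The first principal component, with 48.7% of the variance, separated the groups, with control arrays between -24.7 and -9.62 and knockout arrays between 12.4 and 30.2. Control 3, at -9.62, lay closest to the knockout arrays. Knockout 1, at 12.4, and knockout 2, at 12.7, were the knockout arrays closest to the controls. Correlations over all genes were 0.990 to 0.993 between control arrays, 0.988 to 0.992 between knockout arrays and 0.973 to 0.990 across the groups.

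The sex-specific transcripts of 7 arrays matched the female label, and those of control 1 did not. Xist, the transcript that silences 1 X chromosome in females, was at 6.80 in control 1 against 10.82 for the next lowest control array. The Y-linked genes Eif2s3y, Kdm5d and Uty were at 8.14, 7.41 and 6.49 in control 1, while the next highest control values were 2.99 for Eif2s3y and 4.43 for Kdm5d. Group means ± SD were 9.87 ± 2.05 in controls and 10.73 ± 0.18 in knockouts for Xist, and 4.19 ± 2.63 and 2.83 ± 0.06 for Eif2s3y.

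**Figure D1:**
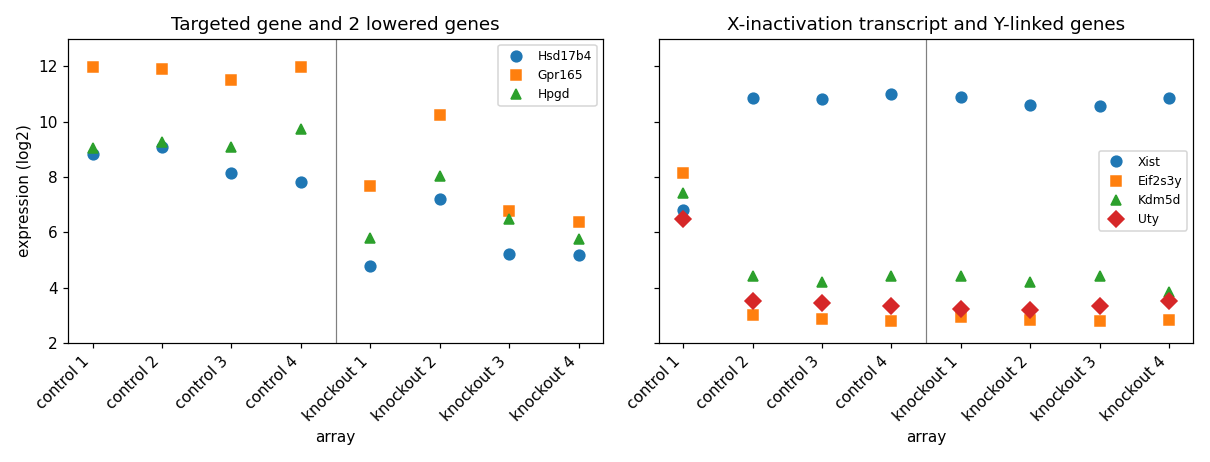
Expression (log2) of Hsd17b4, Gpr165 and Hpgd (left) and of Xist, Eif2s3y, Kdm5d and Uty (right) in each of the 8 arrays, 1 point per gene and array. Knockout 2 lies above the other knockout arrays for the 3 lowered genes, with Hsd17b4 at 7.20, and control 1 has Eif2s3y at 8.14 and Xist at 6.80.

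In knockout microglia 1073 genes were higher and 832 were lower than in controls, 9.55% of those tested. The genes with the highest increases included Cxcl13, a B-cell-attracting chemokine, by 3.70 ± 0.83 (SE) on the log2 scale, the acute-phase protein gene Saa3 by 3.56 ± 0.47, the cystatin gene Cst7 by 3.04 ± 0.39 and Cox6a2, an isoform of a cytochrome c oxidase subunit, by 3.15 ± 0.38. Cd72, a C-type lectin receptor (3.10), Cp, the copper carrier ceruloplasmin (2.73), Gpnmb (2.73), lipoprotein lipase Lpl (2.57), fibronectin Fn1 (2.56) and the receptor tyrosine kinase Axl (2.53) completed the 10 highest. The change of Cxcl13 was 2.64 without control 4 and 4.50 without control 3. The lowest change was that of the orphan receptor gene Gpr165, from 11.85 ± 0.22 (SD, n = 4) to 7.76 ± 1.74, or 17.0-fold. Its log2 change of -4.09 was -4.92 without knockout 2. Hpgd, which degrades prostaglandins (-2.77), Bank1 (-2.15), the semaphorin Sema6d (-2.05), Khdrbs3 (-1.90), the fructose transporter Slc2a5 (-1.89), Klrd1 (-1.83), Gimap6 (-1.77) and the interleukin-7 receptor Il7r (-1.77) also fell. The rule that named these genes took only called genes whose groups did not overlap. That every knockout value lay on one side of every control value is therefore set by the rule. Their adjusted p ran from 0.000209 for Slc2a5 to 0.0139 for Cxcl13.

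At least 2-fold differences were found for 185 higher and 62 lower genes, and the median size of change among the 1905 called genes was 0.57 on the log2 scale. The groups did not overlap for 1768 of the called genes (92.8%) and for 2792 of all 19938 tested genes, where chance gives 2.86% of genes. Without control 3 and knockout 2, an alternative chosen after seeing the data, 1026 genes were higher and 792 lower, and 1583 of the 1905 calls were kept. Leaving out control 1 as well gave 649 higher and 494 lower genes. The count of lower genes fell to 544 without control 1, 517 without control 2 and 507 without knockout 3. The calls of Cxcl13 and Fn1 were lost under an intensity-dependent robust prior (adjusted p = 0.124 and 0.0855).

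**Figure D2:**
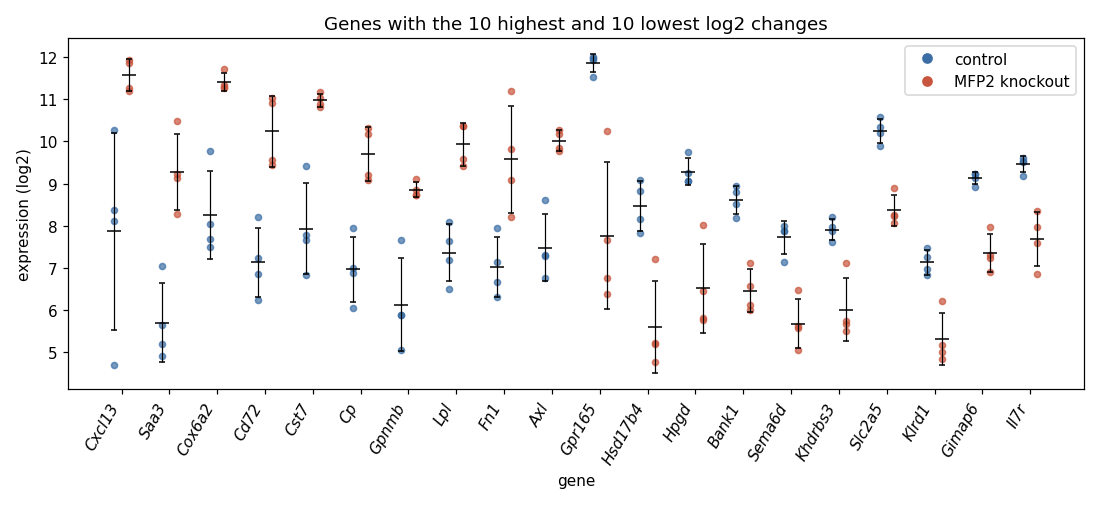
Expression (log2) of the genes with the 10 highest and the 10 lowest log2 changes among called genes whose groups did not overlap. Each point is 1 array (blue for control, red for MFP2 knockout), with the group mean and SD in black (n = 4 each). Gpr165 falls from a mean of 11.85 to 7.76, and Cxcl13 rises from 7.86 to 11.56.

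Control 3 lay between the groups at lowered and raised genes, and knockout 2 at lowered genes. Over 13 genes lowered by more than 2 log2 units in the other 6 arrays, the median linear level of knockout 2 stood 25.7% of the way to the control level, while the other knockout arrays stood at -3.44 to 3.54%. Over 45 raised genes, control 3 stood 21.4% of the way to the knockout level, against -4.27 to 3.99% for the other control arrays. At the lowered genes it stood at 30.5%. The genes were chosen by their change in those 6 arrays, which favours these arrays at their own group's level. The contrast with control 3 and knockout 2 is therefore partly set by that choice. The knockout arrays spread widely at the raised genes, from -35.2% for knockout 4 to 27.1% for knockout 2 and 40.7% for knockout 1.

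**Figure D3:**
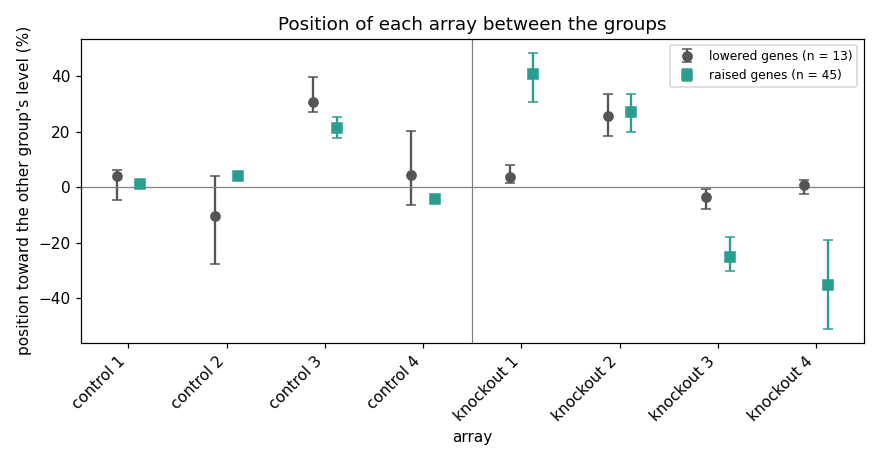
Position of each array between the groups, as the median over 13 lowered and 45 raised genes of its linear level on the way to the other group's level (%), with 95% bootstrap intervals over genes; each array was left out of its own reference. The genes were chosen in the arrays other than control 3 and knockout 2, which favours those arrays at their own group's level. Control 3 stands at 30.5% and 21.4%, knockout 2 at 25.7% and 27.1%, and knockout 1 at 40.7% for the raised genes alone.

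Most of the listed genes that mark resting microglia fell, and most of those that mark microglia around neurodegeneration rose. Of 27 measured homeostatic genes, 23 were lower, 0 were higher and 4 did not pass the test (25 lower when adjusted over the list alone). The purinergic receptor P2ry13, an ADP sensor, fell by 0.82 ± 0.10 (SE, adjusted p = 0.000441), Slc2a5 by 1.89, the adhesion protein Jam2 by 1.28, the ectonucleotidase Entpd1 by 0.96, the cytosolic DNA sensor adaptor Sting1 by 0.80 and Selplg by 0.77. The identity genes Tmem119 (-0.66), Cx3cr1 (-0.50) and P2ry12 (-0.45) were lower as well but kept high levels, Tmem119 at 11.83 ± 0.12 (SD) in knockouts against 12.49 ± 0.10 in controls. Among the general myeloid genes, Aif1 (10.63 against 10.69) and the sort marker Itgam (11.66 against 11.75) did not pass the test, nor did Ptprc, which encodes CD45 (10.34 against 10.07, adjusted p = 0.0895). Itgam was called lower after quantile normalization (adjusted p = 0.0416) and Ptprc higher after cyclic loess (adjusted p = 0.0384). Of 30 neurodegeneration-associated genes, 23 were higher and 0 lower (27 higher when adjusted over the list alone), with a median log2 change of 1.08. The integrin Itgax rose by 2.40 ± 0.26 (SE), Csf1, a growth factor for microglia, from 7.16 to 9.16, the beta-glucan receptor Clec7a by 1.59, the pyrophosphate transporter Ank by 1.11 and the oxygen-sensing transcription factor Hif1a by 1.05, and Axl, Cst7, Lpl, Gpnmb and Cox6a2 belong to the same list. The lists passed camera with a preset correlation (adjusted p = 1.99e-23 for homeostatic and 1.81e-30 for neurodegeneration-associated genes) and fry. The calls were lost with an estimated correlation, at adjusted p = 0.162 with an estimated correlation for the first and adjusted p = 0.120 with an estimated correlation for the second.

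Inflammatory mediators moved in both directions. Of 29 measured pro-inflammatory genes, 9 were higher and 5 lower (11 and 5 when adjusted over the list alone). Saa3 rose most, the cytokine gene Il1b rose by 1.69 ± 0.22 (SE), Il12b, a subunit of interleukin-12 and interleukin-23, by 1.22 and the lipopeptide receptor Tlr2 by 0.80, while the inflammasome sensor Nlrp3 fell by 0.72 ± 0.12 and the endotoxin receptor Tlr4 by 0.50. Of 23 chemokines and their receptors, 10 were higher and 4 lower (12 and 5 when adjusted over the list alone): Cxcl16 rose by 1.32 and the receptor Cxcr4 by 1.14, and Ccl24 fell by 0.95. Alternative-activation genes were also divided, 4 higher and 3 lower of 23 (8 and 5 when adjusted over the list alone), with the growth factor Igf1 higher by 1.26, the scavenger receptor Msr1 higher by 1.45 and the mannose receptor Mrc1 lower by 1.55. Mrc1 and Lyve1, both lower, are shared with the list of brain-border macrophage markers, of which 5 fell. The camera test placed the pro-inflammatory list (adjusted p = 0.0122) and the chemokine list (adjusted p = 0.000428) higher and did not call the alternative-activation list (adjusted p = 0.172). With an estimated correlation these gave adjusted p = 0.409 with an estimated correlation for the pro-inflammatory list and adjusted p = 0.266 with an estimated correlation for chemokines, and fry gave 0.0946 and 0.0752. Msr1 was not called under an intensity-dependent robust prior (adjusted p = 0.0793), the alternative-activation list passed without knockout 1 (adjusted p = 0.0381, or adjusted p = 0.464 with an estimated correlation), and its 4 higher members became 2 without control 1, control 2 or knockout 3.

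Part of the interferon-responsive genes rose. Of 27 measured, 14 were higher and 0 lower (18 higher and 1 lower when adjusted over the list alone), among them Ifi27l2a by 1.30 ± 0.22 (SE), the 2'-5' oligoadenylate synthetase-like Oasl2 by 1.06, the nucleic acid sensor Zbp1 by 0.91 and Rtp4 by 0.85. Antigen presentation had 4 of 18 members higher and 0 lower (5 and 0 when adjusted over the list alone): the class I gene H2-Q4 (1.12), the immunoproteasome subunits Psmb8 (0.53) and Psmb9 (0.50) and the proteasome activator Psme1 (0.33). Complement and Fc receptor genes had 6 higher and 1 lower of 18 (7 and 2 when adjusted over the list alone), including the integrin Itgax (2.40), the Fc receptor Fcgr4 (2.27), complement factor Cfb (1.95) and the anaphylatoxin receptor C3ar1 (1.53). Of 36 lysosomal genes, 12 were higher and 0 lower (16 and 0 when adjusted over the list alone), with the protease genes Ctsl (1.13), Ctsb (0.61) and Ctsz (0.61) and the galactosidase Glb1 (0.94). Camera called the interferon (adjusted p = 3.58e-12), antigen presentation (0.00146), complement (4.25e-05) and lysosomal (1.76e-08) lists. With an estimated correlation the calls were lost, with adjusted p = 0.266 with an estimated correlation for interferon and for lysosome, adjusted p = 0.352 with an estimated correlation for antigen presentation and adjusted p = 0.293 with an estimated correlation for complement, and antigen presentation also missed the threshold by fry (adjusted p = 0.0831). The 14 higher interferon genes became 9 without control 1, control 2, control 4 or knockout 3, the 1 lower complement gene became 0 without control 1, control 2, knockout 1, knockout 2 or knockout 3 and 2 without control 4, and Psme1 was not called without control 1 (adjusted p = 0.0872), control 2 (0.0738), control 4 (0.0758), knockout 3 (0.108) or knockout 4 (0.0815).

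A minority of the remaining peroxisomal genes changed, in both directions. Over all tested genes 9.55% were called. Of 27 genes of peroxisomal lipid metabolism other than Hsd17b4, 2 were higher and 2 lower (2 and 3 when adjusted over the list alone). Abcd2, a peroxisomal importer of very long-chain fatty acids, rose by 0.87 ± 0.12 (SE, adjusted p = 0.000701) and Phyh, the first enzyme of phytanic acid alpha-oxidation, by 0.58, while the ether lipid synthesis genes Agps (-0.58) and Far1 (-0.46) fell. Peroxisome biogenesis genes had 2 higher and 1 lower of 18 by either adjustment, in full and adjusted over the list alone: Fis1, which acts in fission of mitochondria and peroxisomes (0.64), the import receptor Pex7 (0.30) and Pxmp4 (-0.32). Among 28 genes of mitochondrial fatty acid oxidation and PPAR targets, 1 was higher and 0 lower, also when adjusted over the list alone, the fatty acid translocase Cd36 (2.34 ± 0.40, adjusted p = 0.00298). All 3 lists passed fry's test for members that change in either direction (fry adjusted p = 0.000148, 0.000166 and 0.0148). That test does not ask whether a list moves one way. None of these 3 lists passed camera (adjusted p = 0.787, 0.871 and 0.0711), at an unadjusted p of 0.717, 0.820 and 0.0418. The biogenesis list had a median of -0.05 and a mean of 0.01. The third list passed without control 1 (adjusted p = 0.0424), control 2 (0.0357), knockout 1 (0.0195) or knockout 2 (0.0485), and had 2 higher members without knockout 2. In the same order these gave adjusted p = 0.588 with an estimated correlation, adjusted p = 0.587 with an estimated correlation, adjusted p = 0.394 with an estimated correlation and adjusted p = 0.621 with an estimated correlation. Without control 3 the biogenesis list had 1 higher and 2 lower members. Of the peroxisomal lipid genes 1 was lower without control 1, control 2 or knockout 3, and 3 without knockout 2. Far1 was not called without control 1 (adjusted p = 0.0586), control 2 (0.0574) or knockout 3 (0.0568). Pxmp4 was lost without any single array other than control 3 (adjusted p = 0.0551 to 0.103), and Pex7 without any single array other than control 2 (adjusted p = 0.0742 to 0.139), and both also with arrays centred on their medians (adjusted p = 0.0590 and 0.0733).

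Some genes of sterol and fatty acid handling rose. In cholesterol synthesis 4 of 21 members were higher and 0 lower (9 and 1 when adjusted over the list alone), including Dhcr7 (0.65 ± 0.14, SE) and Sc5d (0.50), which act in its last steps, the mevalonate pathway kinase Pmvk (0.45) and the sterol sensor Insig1 (0.53). In cholesterol efflux and LXR targets 6 were higher and 1 lower of 17 (8 and 2 when adjusted over the list alone): the apolipoprotein Apoc1 by 2.47, the cholesteryl ester hydrolase Nceh1 by 1.73 and the 25-hydroxylase Ch25h by 1.38, against Mylip, which marks the LDL receptor for degradation, lower by 0.76. In fatty acid synthesis, elongation and desaturation 4 of 25 were higher and 0 lower (5 and 0 when adjusted over the list alone), with the desaturase Scd1 (1.32) and acetyl-CoA carboxylase Acaca (1.28) ahead of the desaturases Scd2 and Fads2. Camera called the 3 lists (adjusted p = 3.30e-05, 0.00586 and 0.00752). The calls were lost with adjusted p = 0.266 with an estimated correlation, adjusted p = 0.351 with an estimated correlation and adjusted p = 0.409 with an estimated correlation in the same order, the second also by fry (adjusted p = 0.0565) and the third by fry (0.0946) and without dim genes (0.187). The 4 higher fatty acid synthesis genes became 2 without control 1, control 4 or knockout 4 and 6 without knockout 1, with 1 lower without knockout 4. The 4 cholesterol synthesis genes became 6 without knockout 1 and 7 after cyclic loess scaling, with 1 lower without control 3, and the 1 lower efflux gene became 2 without knockout 4. Insig1 was not called without control 1 (adjusted p = 0.0971), control 3 (0.0892), control 4 (0.112), knockout 3 (0.122) or knockout 4 (0.0976), nor with arrays centred on their medians (0.0536). Scd2 was lost without control 1 (adjusted p = 0.0891), control 3 (0.0634), control 4 (0.0736), knockout 3 (0.0873) or knockout 4 (0.0718), and Fads2 without control 1 (0.126), control 2 (0.0594), control 3 (0.0590), control 4 (0.102), knockout 2 (0.0886) or knockout 4 (0.0897).

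Most ribosomal protein genes and many genes of energy metabolism rose. Of 31 measured ribosomal protein genes 29 were higher and 0 lower, the same by adjustment over all genes and adjusted over the list alone, with a median log2 change of 0.75. Rps18 rose by 1.15 ± 0.14 (SE), Rpl19 by 0.96, Rplp0 by 0.94 and Rps2 by 0.82. Of 23 genes of glycolysis and the hypoxia response 17 were higher and 0 lower, also when adjusted over the list alone, with Hif1a, the aldolase Aldoa (0.99), Pgam1 (0.90) and phosphofructokinase Pfkl (0.88). Oxidative phosphorylation had 21 of 41 higher and 0 lower (27 and 0 when adjusted over the list alone), among them the complex I subunits Ndufa1 (1.10) and Ndufa2 (0.69) and the cytochrome c oxidase subunits Cox4i1 (0.93) and Cox8a (0.92). Camera called the ribosomal (adjusted p = 1.20e-33), glycolysis (4.61e-18) and oxidative phosphorylation (4.81e-17) lists, as did fry. The calls were lost with adjusted p = 0.120 with an estimated correlation for the first and the second and adjusted p = 0.266 with an estimated correlation for the third. The 21 higher oxidative phosphorylation genes became 13 without control 2, 12 without knockout 3 and 13 without knockout 4.

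Some genes of the amino acid and oxidative stress responses rose as well. Of 27 genes of the ER and amino acid stress response, 13 were higher and 2 lower (14 and 3 when adjusted over the list alone). Those with the lowest adjusted p act in amino acid and folate metabolism or transport: asparagine synthetase Asns by 2.33 ± 0.21 (SE, adjusted p = 0.000169), the serine synthesis enzyme Psat1 from 6.45 to 7.95, the mitochondrial folate enzyme Mthfd2 by 1.11 and the amino acid transporter Slc7a5 by 0.98. The lower members were Xbp1 (-0.43), a transcription factor of the unfolded protein response, and the ER chaperone Hsp90b1 (-0.35), both named after their values were seen; 1 lower member was left without any single array other than knockout 4. In antioxidant defence 11 of 25 were higher and 0 lower (13 and 0 when adjusted over the list alone), with glutathione peroxidase Gpx3 (1.70), Gsto1 (1.10), Prdx1 (0.76) and the cystine transporter Slc7a11 (0.53). Trophic and growth factors had 7 higher and 0 lower of 20 (7 and 2 when adjusted over the list alone), namely Csf1, Igf1, Vegfa (0.87) and progranulin Grn (0.37) among them. Camera called the 3 lists (adjusted p = 7.99e-09, 2.50e-09 and 0.00784), as did fry. They were lost with adjusted p = 0.120 with an estimated correlation, adjusted p = 0.180 with an estimated correlation and adjusted p = 0.266 with an estimated correlation, in that order. The 11 antioxidant genes became 7 without control 1 and 5 without knockout 3, and the 7 trophic genes became 4 without control 4.

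Few cell cycle genes passed the test, in opposite directions. Of 40 measured, 1 was higher and 1 lower, also when adjusted over the list alone: the kinetochore motor Cenpe rose by 0.52 ± 0.11 (SE) from a low level of 4.72, and the G1 cyclin Ccnd1 fell by 0.97 ± 0.13 from 10.26. The list passed camera (adjusted p = 0.000114) with 35 of its members above 0, and the call was lost by fry (adjusted p = 0.341), without dim genes (0.0609) and with adjusted p = 0.557 with an estimated correlation. Without knockout 1 the number of higher members rose from 1 to 9, and it was 2 without control 2 and 3 without control 3 or knockout 2; the lower members were 2 without knockout 3. Of 25 genes of the dissociation and immediate-early response, which respond to tissue handling, 1 was higher (Egr2, 1.04) and 1 lower (the heat shock gene Hspa1a, -0.64), also when adjusted over the list alone. Without knockout 1 there were 2 higher members. That list did not pass camera (adjusted p = 0.982), except that it was higher without control 4 (adjusted p = 0.000898, or adjusted p = 0.549 with an estimated correlation), the array with the highest mean level of the list (8.61, against 7.10 to 7.45 in the other controls and 7.19 to 7.84 in knockouts), when 5 of its members were higher and 0 lower. Hspa1a was not called without control 1 (adjusted p = 0.0508) or control 4 (0.0541).

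**Figure D4:**
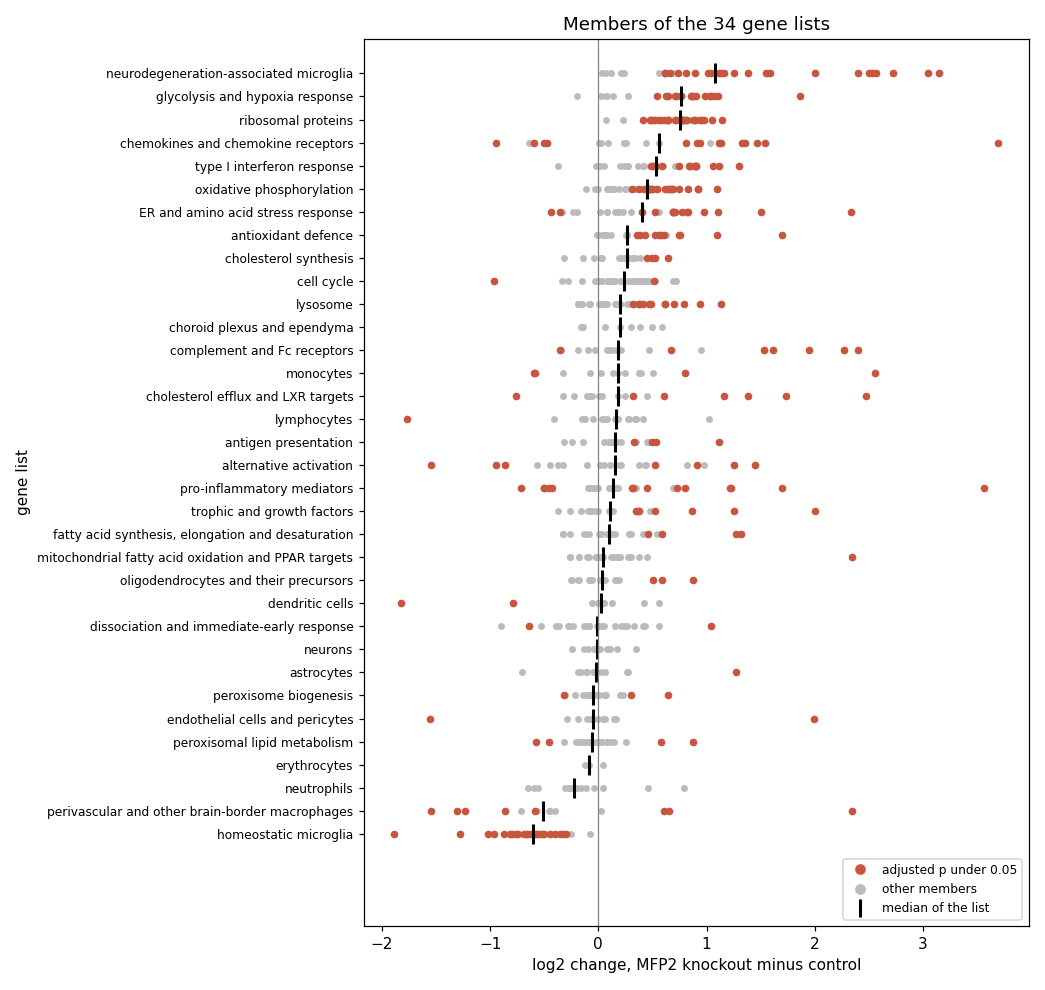
Log2 change (MFP2 knockout minus control) of each measured member of the 34 gene lists, ordered by the median of the list (black bar); red points have an adjusted p under 0.05 over all genes and grey points do not. The neurodegeneration-associated list has a median of 1.08 and the homeostatic list one of -0.60.

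Markers of brain-border macrophages moved in both directions, with more lower than higher. Of 14 measured, 5 were lower and 3 higher (9 and 3 when adjusted over the list alone). The scavenger receptor Stab1 fell by 1.23 ± 0.16 (SE), the platelet factor Pf4 by 1.30 and Mrc1 by 1.55, whereas Cd36, shared with the PPAR targets, rose. Camera called the list lower (adjusted p = 0.00752), a call lost by fry (adjusted p = 0.0946), without dim genes (0.0899) and with adjusted p = 0.454 with an estimated correlation. The 5 lower members became 3 without control 1, control 2 or knockout 3. Monocyte markers were divided, with Fn1 and Ms4a4c (0.80) higher and the chemokine receptor Ccr2 (-0.59) and F13a1 (-0.59) lower of 13 (5 higher and 2 lower when adjusted over the list alone), and camera gave an adjusted p of 0.172, or 0.0312 without knockout 1, where it was adjusted p = 0.608 with an estimated correlation. Ms4a4c was not called without any single control array (adjusted p = 0.0687 to 0.112) or without knockout 3 (0.0708), nor under a robust prior (0.0909). F13a1 was not called without control 1 (adjusted p = 0.0678), control 2 (0.0900), control 3 (0.0729), knockout 1 (0.0543) or knockout 3 (0.0873).

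None of 14 neutrophil markers was called by limma over all genes or adjusted over the list alone. Their signal was not low, however. The mean level of the list was 8.51 in controls and 8.36 in knockouts, the highest of the cell type lists. It varied between arrays, from 7.24 in control 1 to 9.46 in control 3. Whether neutrophils among the sorted cells gave this signal was not tested. The calprotectin genes S100a8 and S100a9, singled out after their values were seen, were at 11.67 ± 1.24 (SD) and 11.73 ± 1.17 in controls and 11.55 ± 0.41 and 11.53 ± 0.34 in knockouts. The members with the lowest p were Elane (5.86 and 5.61, adjusted p = 0.406) and Ltf (9.06 and 8.41, adjusted p = 0.498), so that 0 passed an unadjusted p under 0.05, and camera gave an adjusted p of 0.629. Without control 1 the list was lower in knockouts (adjusted p = 0.000118, or adjusted p = 0.411 with an estimated correlation), with 3 members called lower, among them Ltf (adjusted p = 0.0104). Without control 1, control 3 and knockout 2 it was lower as well (adjusted p = 0.000396, or adjusted p = 0.479 with an estimated correlation). Among lymphocyte markers Il7r was lower and 17 of 18 did not pass, also when adjusted over the list alone, and among dendritic cell markers Klrd1 and Cd209a (-0.79) were lower of 10 (1 higher and 2 lower when adjusted over the list alone). Cd209a was not called without control 1 (adjusted p = 0.0588), control 3 (0.0567) or knockout 3 (0.0607). The lymphocyte list had 2 higher members without control 3, 1 without knockout 1, knockout 2 or knockout 3, and 2 lower members without control 1. The dendritic cell list had 1 higher member without knockout 1. Camera gave adjusted p = 0.351 for lymphocytes and 0.898 for dendritic cells, the latter with a median of 0.02 and a mean of -0.15.

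The mean levels of the neuronal, astrocyte, oligodendrocyte and endothelial lists lay between 5.16 and 5.83 in either group, while single members such as Mbp, at 7.16 in controls and 7.75 in knockouts, and Pecam1, at 7.57 in controls, were higher. No neuronal marker of 16 was called by limma, and 1 passed an unadjusted p under 0.05, Snap25 (5.98 and 6.33, adjusted p = 0.149), followed by Stmn2 (4.96 and 5.13, adjusted p = 0.335). The astrocyte gene Gfap rose by 1.28 ± 0.20 (SE) to 6.69, as 1 of 13, and Mbp (0.59), Cspg4 (0.88) and Bcas1 (0.51) rose as 3 of 16 oligodendrocyte-lineage markers. Of 14 endothelial and pericyte markers, the adhesion molecule Pecam1 fell by 1.56 and the VEGF receptor Flt1 rose by 1.99. Adjusted over the list alone the counts were 0, 1 and 3 higher for neurons, astrocytes and oligodendrocytes and 1 higher and 2 lower for endothelial cells. None of 3 erythrocyte markers passed (adjusted p = 0.507 for Epb42 and 0.783 for Slc4a1), nor did any of 9 choroid plexus and ependymal markers (adjusted p = 0.277 for Folr1 and 0.299 for Otx2), by limma over all genes or adjusted over the list alone, and 0 of either list passed an unadjusted p under 0.05. Camera called none of these lists, with adjusted p = 0.685 for neurons, 0.774 for astrocytes, 0.267 for oligodendrocytes, 0.739 for endothelial cells, 0.776 for erythrocytes and 0.467 for choroid plexus, the last called without knockout 3 (adjusted p = 0.0129, or adjusted p = 0.398 with an estimated correlation), where 3 members were higher, among them Folr1 (0.0424) and Otx2 (0.0472). The median and the mean had opposite signs for neurons (-0.01 and 0.02), astrocytes (-0.02 and 0.04) and endothelial cells (-0.05 and 0.00136). Cspg4 was not called without control 2 (adjusted p = 0.0598), knockout 3 (0.0639) or knockout 4 (0.0519), nor Bcas1 without knockout 4 (0.0570).

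Genes near Hsd17b4 were no more often changed than others. A targeted allele can carry neighbouring DNA of another strain, so the 100 tested genes on each side were compared with the rest. Among these 200 genes 18 were called (9%), against 1886 of 19737 elsewhere (9.56%), an odds ratio of 0.936 (two-sided Fisher's exact test, p = 0.904). The called neighbours included the complex I gene Ndufa2 (0.69) and the homeostatic receptor gene Csf1r (-0.35).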

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

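The shares at lowered and raised genes, the level of Eif2s3y, the correlations of single pairs of arrays and the Hsd17b4 difference were chosen as tests after these arrays were seen to stand apart; the splits of the samples were planned. Each group of 4 values of the named genes was searched for an array far from the others (gap to the nearest value over the range, above Dixon's 95% critical value). Of 262 groups 17 stood out, where chance gives about 1 in 20, or 13.1.

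Control 1 stood apart at the sex-specific genes Eif2s3y (0.961), Xist (0.960), Uty (0.947) and Kdm5d (0.932). Its values on the first principal component (-23.9) and for Hsd17b4 (8.83) lay among those of the other controls. Whether its sex label is wrong or the sample was mixed or exchanged was not tested and stays open, which leaves the makeup of the control group uncertain by 1 array.

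Control 3 was the outlying array at 9 genes, and at each of them it lay toward the knockout mean: Ifi27l2a (0.984), Apoc1 (0.933), Flt1 (0.917), Rps18 (0.907), Cox4i1 (0.885), Cxcr4 (0.865), Sema6d (0.859), Asns (0.852) and Gpr165 (0.841). Knockout 2 was outlying at Khdrbs3 (0.853), toward the control mean. The single remaining cases were Cspg4 (0.945) and Pex7 (0.860) at control 2 and Otx2 (0.860) at knockout 3.

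At lowered genes knockout 2 and control 3 lay between the groups, and control 3 did so at raised genes as well. At 13 genes lowered by over 2 log2 units in the other 6 arrays the median linear level of knockout 2 stood 25.7% of the way to the control level (95% bootstrap interval 18.5 to 33.3), and at 45 raised genes control 3 stood 21.4% of the way to the knockout level (17.7 to 25.3) and 30.5% at the lowered genes; at raised genes the knockout arrays spread from -35.2 to 40.7%, and knockout 2 (27.1%) was not set apart there, since knockout 1 stood at 40.7%. The genes were chosen by their change in the other 6 arrays, which favours those arrays at their own group's level. That choice can leave the held-out arrays between the groups, and its part in the values was not tested. RNA of the other group in knockout 2 and control 3 may account for the values as well. RNA of control 1 in knockout 2 would not, since Eif2s3y was at 2.81 there. An exchange between the 2 samples cannot be told apart from other causes: over genes that vary between animals their correlation, 0.622, was the highest of 16 pairs, but its interval (0.513 to 0.744) overlapped that of the next pair (0.505, 0.262 to 0.684). A milder response in knockout 2 cannot be told apart from a mixed sample either, since Hsd17b4 was 1.99 above the other knockout arrays but its probe set need not lie in the deleted part.

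The correlation test was revised after its value was seen. The form written before that value was seen asked for a correlation above 0.3 that was the highest of the pairs, which 0.622 met, but it took a single reference for all pairs and so did not treat them alike. A second form, with each pair treated alike, asked that the lower bound exceed the next correlation, which it met narrowly (0.513 against 0.505). The form kept asks for intervals that do not overlap, and that was not met.

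Chance is argued against as the source of a count as high as 1905 called genes. Of the 35 splits of the 8 arrays into 4 and 4, 1 reached as many, the real one, and the highest other split called 0. That is the smallest share the splits can give, every other split mixes the genotypes, and single genes are not covered. By the same count chance could not be excluded for the number of gene lists. Of the 35 splits 7 called at least as many lists as the real 19, with up to 23 in another split. The 6 others all had 3 arrays of one genotype on each side; of the 18 splits with 2 of each genotype on each side, 0 reached 19 and the highest called 17.

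The 7085 probe sets with several or no gene names were outside the comparison. Fitted together with all others, 608 of them were higher and 194 lower in knockouts, and they are not named here.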

How the results depend on the processing

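The exclusion of control 3 and knockout 2, and of control 1 with them, the estimated correlation with arrays left out and, for the neighbours of Hsd17b4, every alternative other than 50 or 200 genes were chosen after the data were seen. The counts of 1073 higher and 832 lower genes moved by more than 1.5 times with at least 1.5-fold change (597 and 313), with an adjusted p under 0.01 (567 and 358), with a plain two-sample test (377 and 271), with all probe sets (1909 higher) and without the 3 arrays named above (649 and 494). The fold and p thresholds are stricter and the last setting has fewer samples by construction. The fit of all probe sets counts 28874 probe sets in place of 19938 genes. Of its 1909 higher calls, 608 were probe sets with several or no gene names. For the plain test the cause was not tested. Leaving out single arrays gave 753 to 1162 higher and 507 to 960 lower genes. Under the other alternatives run the counts stayed within 1.5 times, and calls shared with the refits over named genes kept their direction. Of the 130 named genes, 36 of 1283 values under the other refits and 57 of 1040 with an array left out lost the call. In the same order 3 and 3 gained it, and 0 reversed. The plain two-sample test, the fold and p thresholds and all probe sets gave counts alone and are outside this tally.

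Of the lists, 17 were higher and 2 lower; with an estimated correlation 0 were higher and 0 lower, also in each fit with arrays left out, by fry 11 were higher and 1 lower, and without dim genes 1 was lower. The list of the dissociation and immediate-early response, at an adjusted p of 0.982, was higher in knockouts without control 4 (adjusted p = 0.000898, or adjusted p = 0.549 with an estimated correlation; range 0.000898 to 0.876 with single arrays left out), and the mean level of the list was highest in control 4 (8.61, next 7.84 in a knockout array), but the cause of that level was not tested. Hsd17b4 stayed lower and past the threshold in each refit that gave its own result. The plain two-sample test and the fit of all probe sets gave counts alone, so its call there is not reported. The comparison of its neighbours never passed, with odds ratios of 1.17 for 50 and 1.02 for 200 genes on each side as planned, and of 0.535 to 1.11 under the alternatives added later.

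Replicate numbers are shared by the groups, but arrays of one number did not deviate together (correlations of 0.158, -0.0645, 0.00590 and 0.00780), and among the 8 arrays control 1 and knockout 1 alone correlated best with their own number. With the replicate number as a block 1029 genes were higher and 826 lower, with 1666 calls kept, 239 lost and 189 new. For arrays the signal over background limits dim genes, and 4 arrays per group limit small changes. In the simulation, with fewer changed genes and independent noise, 52.0% of changes of 0.5 log2 units were recovered.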

Other observations

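The tests of matched random lists and of genes near Hsd17b4 were planned. The tests of gene families in any split, of gene length and of border macrophage markers were chosen after the results were seen. So were most alternatives for the genes near Hsd17b4. A search of 465 gene families with at least 6 tested members sharing a symbol stem (Fisher's exact test per direction, adjusted over 930 tests) found 16 family tests past the threshold. Fisher's test takes genes as independent, while the correlation within the Rpl family was estimated at 0.434, so this number alone, which was at first taken to exclude a chance concentration of calls, leaves it undecided. With the 1905 genes of lowest p taken in each of the 35 splits of the arrays, the real split alone reached 16 family tests. The next, with 3 arrays of one genotype on each side, reached 14, and the highest with 2 of each reached 6. First of 35 is the smallest share this test can give. It argues against chance for the number of families without excluding it. For single families, as many members in one direction were found in 1 split for Gstm and Arhgap, 2 for Tomm and 3 for Dock. It was 4 for Eif, Gimap, Cd and Ifi, 6 for Mrpl and 12 for Zfp, the real split included. Of the splits with 2 of each genotype on each side, 0 reached as many for Gstm, Arhgap, Tomm, Dock, Cd and Ifi. For Eif, Gimap and Zfp 1 did, and for Mrpl 2 did. The families were picked by the calls of the real split, which favours it, and the counts are not adjusted over families. They therefore exclude chance for no single family. Beyond the ribosomal and respiratory chain families, 5 of 10 Tomm genes, which encode the import channel of the outer mitochondrial membrane, were higher (Fisher adjusted p = 0.00928). So were 10 of 48 Mrpl genes of the mitochondrial ribosome (Fisher adjusted p = 0.0166). The same held for 10 of 49 genes with the stem Eif (Fisher adjusted p = 0.0182) and 4 of 7 Gstm glutathione transferase genes (Fisher adjusted p = 0.0183). The Eif count includes Eif4ebp1, which is not an initiation factor and is also in the ER and amino acid stress list. Of 94 genes with the stem Cd 18 were higher (Fisher adjusted p = 0.000305) and 6 lower. Of 15 Ifi genes 5 were higher (Fisher adjusted p = 0.0496) and 0 lower. The families, chosen after their values were seen, kept the sign of their medians under each scaling (Tomm 0.25, Gstm 0.39).

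Lower families included zinc finger genes, with 35 of 347 Zfp genes (adjusted p = 0.000220, median -0.15), and the Gimap GTPases, with 4 of 8 (adjusted p = 0.0166, median -0.25): Gimap6, Gimap1, Gimap5 and Gimap9. Of 10 Dock genes, which encode exchange factors for small GTPases, 4 were lower (adjusted p = 0.0322, median -0.23). Of 35 Arhgap genes 7 were lower (Fisher adjusted p = 0.0322, median -0.03) and 2 higher. These medians kept their sign under each scaling. Family members overlap with the fixed lists, and calls within a family are not independent.

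The ribosomal, respiratory chain and glycolysis lists were higher by medians of 0.75, 0.45 and 0.76, and their calls were lost with adjusted p = 0.120 with an estimated correlation, adjusted p = 0.266 with an estimated correlation and adjusted p = 0.120 with an estimated correlation. A shift of all abundant genes by the normalization is argued against, since the central 95% of the medians of 10000 random lists matched on mean level reached at most 0.0941. A shift of all short genes in amplification is argued against as the whole cause: the 56 list members that were not among the shortest genes had a median of 0.54 (0.42 to 0.64) and 34 of them were called higher, while 277 other short abundant genes had a median of 0.14 and 2047 longer ones -0.07. The test of length written before compared the other short genes alone, and their 0.14 lay between its limits and left it undecided; the comparison of longer members replaced it after the values were seen. Genes were not matched on length, so the 56 members may still be shorter than the 2047 longer genes. Part of the rise may therefore follow gene length, and shorter members had a median of 0.71 against 0.54. Members of these lists were called between the genotypes, but whether the lack of MFP2 itself caused the rise stays open.

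Border macrophage markers were lower on balance, and fewer border macrophages among the sorted cells may be a source, though the gate on intermediate CD45 would remove cells with high CD45, as border macrophages mostly are. Of the 8 called markers 3 were higher (Cd36 2.34, Ms4a7 0.65 and Colec12 0.61), which that source alone would not give, but microglia can express these genes, so the cause cannot be told apart. Mrc1, Pf4 and Stab1 stood at 6.55, 5.53 and 8.14 in knockouts.

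Flanking DNA of the targeted allele was tested as a source of the changes. Genes near Hsd17b4 were not called more often than others (odds ratio 0.936, with 1.17 and 1.02 for 50 and 200 genes on each side, and 0.535 to 1.11 under the alternatives added later), which leaves single neighbours open.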
